A study of Homo sapiens with 20 samples.

How the data were processed

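Total RNA of Rh30 and Rh41, both alveolar rhabdomyosarcoma cell lines with a PAX3-FOXO1 fusion gene, was extracted with a spin column kit, labelled from an input of 125 ng and hybridised to 20 Affymetrix Clariom S human arrays, per the labels. The values are log2 signals per probe set, as deposited by the authors, and run from 2.22 to 14.22. GCOS is the processing tool the labels name. Its version and the background, summarization and normalization methods are not given in the sources used here. The values were used as deposited. The number of arrays, 2 or 3 per group, limits the precision.

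The value table holds 24351 probe sets. Of these, 17709 carry 1 gene symbol, all of whose Entrez identifiers matched the current gene table, and 6642 carry none. A gene with several probe sets was represented by the one with the highest mean over all arrays, which left out 22 second probe sets and gave 17687 genes tested. The 3739 transcript probe sets without a gene name were tested apart. Background was taken from 23 control probe sets of each array.

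The 8 groups were Rh30 with a control or a KDM4B short hairpin RNA (2 arrays each), Rh30 with a control or a KDM4C small interfering RNA (2 each), and Rh30 and Rh41 with DMSO or QC6352 (3 each). The labels of 10 Rh30 arrays give 2 different groups. The first line of the description, the submitters' sample name, differs from the title, the source name, the treatment and the second line of the description. One of these titles reads shRNA where the source name and the second line of the description of that array read siRNA. By title this array was placed with the siRNA group as siKDM4C replicate 2. Its sample name reads QC6352 replicate 1 of Rh30. Before the data were examined, the design, the alternatives, the rule for named genes and the gene lists were fixed, with the groups by sample name as the first choice and the groups by title as an alternative for every comparison except that of the KDM4B hairpin. Both groupings are reported. Values of single genes and gene lists follow the titles, a preference taken after the values were seen.

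Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, all 20 arrays in 1 fit of 8 group means, 12 residual degrees of freedom). P values were adjusted by the Benjamini-Hochberg method over the 17687 genes, with a threshold of 0.05. Each fold change is the treated minus the control group mean, on the log2 scale, with its standard error (SE). The contrasts were knockdown against its control, QC6352 against DMSO in each line, the difference of these responses (Rh41 minus Rh30), and DMSO in Rh41 against Rh30. The p values measure the spread between arrays that the labels call biological replicates. The numbers of the replicates were not shown to pair the arrays, so they entered only as an alternative.

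The 33 gene lists were written from textbook knowledge and tested with camera from limma at a preset correlation between genes of 0.01, with p adjusted over the lists, and again with the correlation estimated from the data. Their members were counted past the threshold over all genes and adjusted over the list alone. Marker lists of epithelial, blood, endothelial and fibroblast cells were among them. Lists can share members, as those of PAX3-FOXO1 targets and myogenic regulators do with SOX8 and MYOD1, so their calls are not all separate results. Shared calls of 2 comparisons were set beside the number expected from the product of their counts over the genes tested. This number assumes independent calls, although the tests of all comparisons share the same residual spread of a gene, so it can be too low.

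Named genes were chosen by a fixed rule. It took KDM4A to KDM4E, up to 6 rises and 6 falls with the largest fold change past the threshold whose groups of arrays do not overlap, the 2 members with the largest change in each list called, and the 3 largest changes among PAX3-FOXO1 targets, myogenic regulators and muscle structural genes. For the difference between lines and for DMSO it took the 5 largest each way, and for shared calls up to 6 per direction. Symbols starting with LOC, LINC, MIR or SNOR or containing orf were left out. Where fewer than 5 genes passed, it took the 5 with the smallest p. Genes named outside the rule are said to be so where they stand.

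The alternatives were quantile normalization, centring each array on its median, leaving out the lowest 40% of probe sets by mean, eBayes with trend and robust, array weights, a fit of the compared arrays alone, the replicate number as a block, an added fold threshold of 1.5, every probe set with a symbol, the other grouping, and leaving out each array in turn. Repeating them with the groups by title was added after the data were seen. The fit was tested on simulated data with known changes, with groups by title. It recovered 80.6% to 97.0% of 2-fold changes and 50.7% to 65.7% of 1.5-fold changes over the 4 treatment comparisons, with 7 to 13 false calls of 17687 genes. The only list shifted in the simulation was called in all 4, and 0 of the other 32 lists were. The simulated noise was independent between genes and equal in all arrays of a gene. It therefore does not test false calls of lists whose genes are correlated, or arrays of unequal spread. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.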

Results

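The arrays measured gene expression in rhabdomyosarcoma cells in which KDM4 demethylases, which remove methyl groups from lysines of histone H3, were knocked down or inhibited. Rh30 cells carried a hairpin against KDM4B or a control hairpin for 72 h (n = 2 and 2 arrays) or received siRNA against KDM4C or a control siRNA for 72 h (2 and 2). Rh30 and Rh41 cells received the KDM4 inhibitor QC6352 at 200 nM or the vehicle DMSO for 48 h (3 and 3 in each line). Array medians lay at 6.72 to 6.75 log2 in the 4 arrays titled siRNA, at 6.95 to 6.99 in the other 10 Rh30 arrays and at 7.22 to 7.25 in the 6 Rh41 arrays. The median of the background probe sets was 3.64 to 4.01 log2 per array.

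The labels of 10 Rh30 arrays contradict each other, so the target genes were examined first. KDM4B, the target of the hairpin, was at 6.01 and 6.15 log2 in the knockdown arrays against 6.74 and 7.30 in their controls, arrays whose labels do not conflict. KDM4C was at 6.25 and 6.32 log2 in the arrays titled siKDM4C against 6.48 and 6.54 in those titled siControl. The arrays titled DMSO in Rh30 lay at 6.12, 6.26 and 6.90, a span that holds the levels titled siKDM4C. With groups by sample name KDM4C was at 6.42 and 6.69 under siKDM4C against 6.12 and 6.52 under siControl, so this gene does not settle which labels hold. MYOG, the gene of the muscle transcription factor myogenin, was at 9.03 to 9.34 log2 in the 3 Rh30 arrays titled QC6352 and at 11.26 to 11.82 in all other Rh30 arrays. By sample name those 3 arrays are siControl replicate 2 and both replicates of siKDM4C. Across genes, the fold changes of QC6352 in Rh30 and in Rh41, whose labels do not conflict, had a Pearson r of 0.527 (Spearman rho 0.432) by title and -0.0232 by sample name, where genes are not independent replicates. All gene and list values that follow use the titles unless the sample name is given as the grouping, and the counts of genes called by sample name stand in each comparison.

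**Figure D1:**
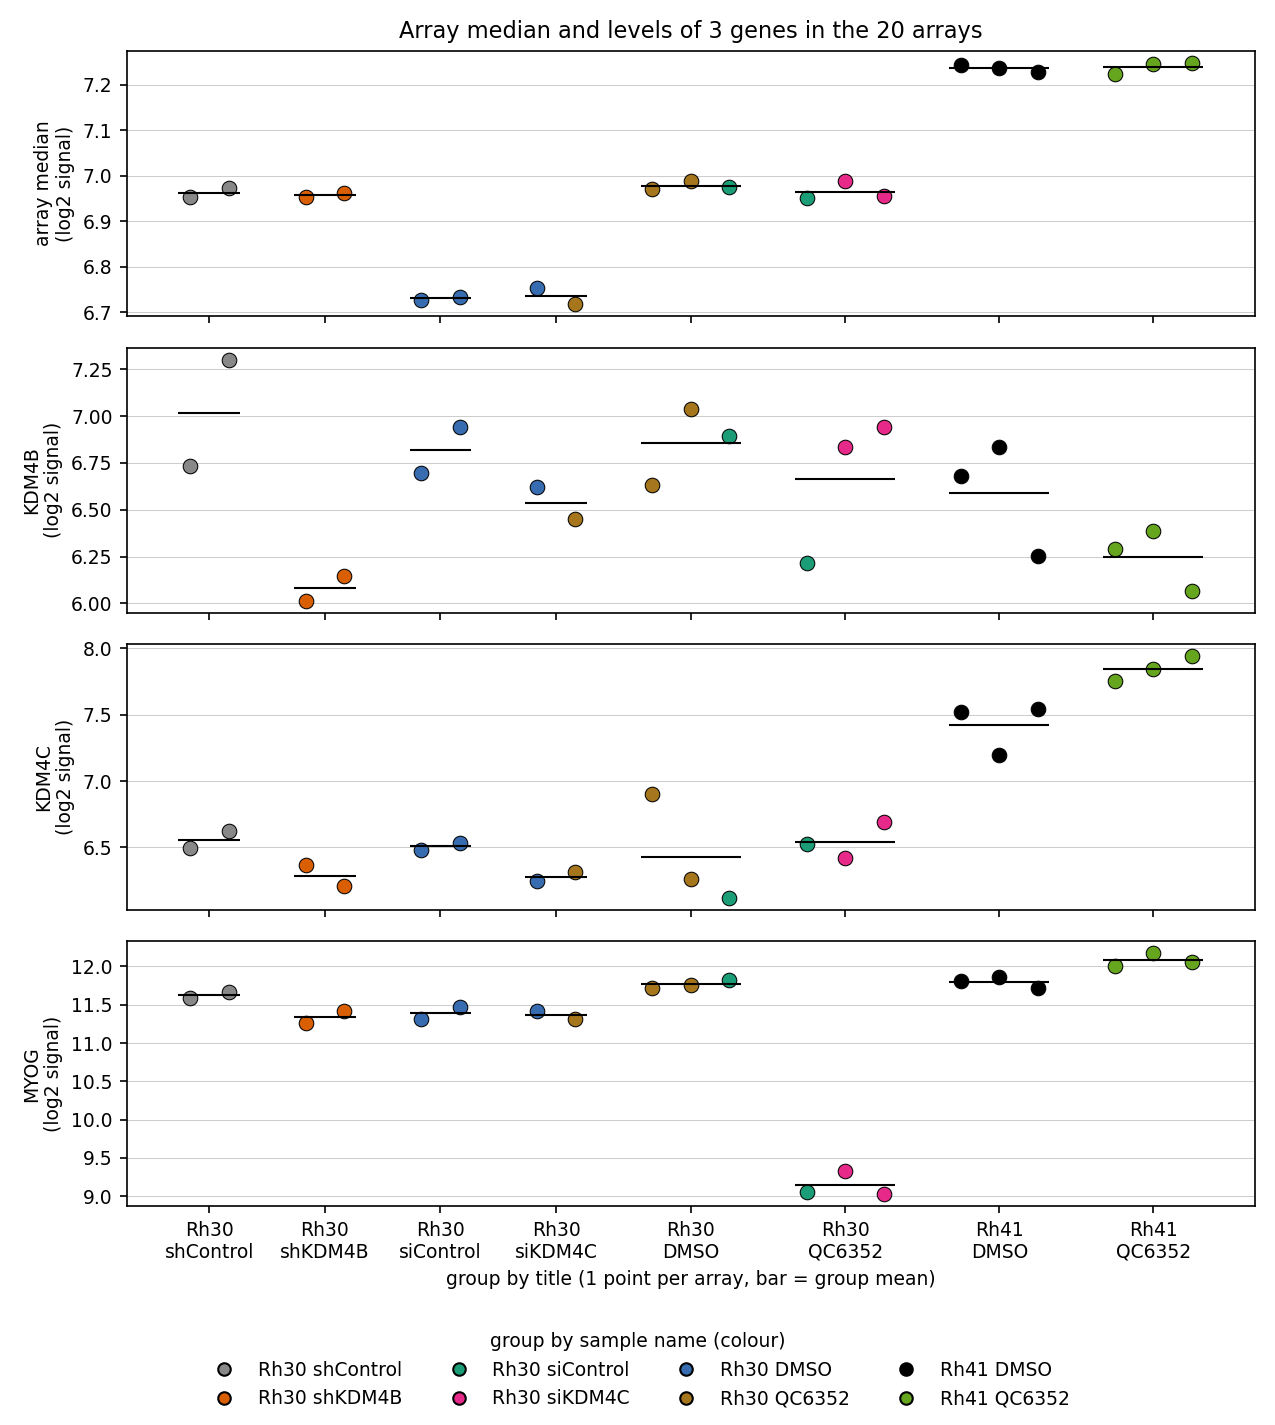
Each point is 1 array, drawn in its group by title and coloured by its group by sample name, with a bar at the group mean; the vertical axes give log2 signal of the array median, KDM4B, KDM4C and MYOG. The 3 arrays titled QC6352 in Rh30 hold MYOG at 9.03 to 9.34 log2, and they carry sample names of the siRNA groups.

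The hairpin comparison asks which genes change with a hairpin against KDM4B in Rh30. The groups hold no rescue of KDM4B and set no further hairpin apart. Effects through KDM4B and other effects of the hairpin therefore cannot be told apart. KDM4B fell by 0.94 log2 (SE 0.23, adjusted p = 0.0120, n = 2 and 2). The largest rises were in TRAF1, a signalling adaptor of TNF receptors (log2 fold change 2.30 ± 0.16 SE), the cystine transporter SLC7A11 (2.19 ± 0.24), the tight junction gene CLDN1 (2.18 ± 0.16), the glucose transporter SLC2A3 (2.06 ± 0.17), GLIPR1 (2.01 ± 0.26) and the Wnt antagonist DKK1 (1.87 ± 0.25). HTATSF1 dropped by 2.85 log2 (SE 0.12), followed by the mitotic gene HMMR (-2.07 ± 0.15), the centrosome gene CNTRL (-2.06 ± 0.39, lower level near background), AZI2 (-2.05 ± 0.22), ARHGEF6 (-1.95 ± 0.13) and AIDA (-1.95 ± 0.14). KDM4D was higher (0.94 ± 0.28, adjusted p = 0.0343) at 5.44 against 4.49 log2, close to background. KDM4C had a fold change of -0.27 ± 0.19 and KDM4A of 0.02 ± 0.13, neither past the threshold.

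Genes of dividing cells fell under the KDM4B hairpin. Of 60 replication-dependent histone genes 18 fell and 0 rose (29 and 0 adjusted over the list alone; camera adjusted p = 1.01e-13), with H4C1 at -1.45 ± 0.24 and H2AC15 at -0.91 ± 0.17. Of 55 genes of G2/M and mitosis 17 fell and 1 rose (27 and 1 adjusted over the list alone; adjusted p = 3.39e-12), among them TOP2A (-1.24 ± 0.12). Of 48 genes of G1/S and DNA replication 16 fell and 0 rose (20 and 0 adjusted over the list alone; adjusted p = 1.67e-08), among them USP1 (-0.99 ± 0.16) and CLSPN (-0.94 ± 0.13). Of 29 genes of ATF4 and the unfolded protein response 14 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 1.67e-08), led by SLC7A11 and the pseudokinase gene TRIB3 (1.22 ± 0.15). The metallothionein and iron list had 8 of 14 members higher and 0 lower (8 and 0 adjusted over the list alone), with the transferrin receptor TFRC at 1.08 ± 0.11 and SLC11A2 at 0.82 ± 0.22. NF-kB and inflammatory genes rose in 7 of 21 cases (8 adjusted over the list alone), with TRAF1 and LIF (0.78 ± 0.15), and fell in 0. MAPK and immediate early genes rose in 8 of 23 and fell in 1 (11 and 1 adjusted over the list alone), with SPRY1 (0.76) and DUSP1 (0.75) up. Matrix and TGF-beta genes rose in 9 of 26 and fell in 0 (11 and 0 adjusted over the list alone), with LOX at 1.47 ± 0.22 and CCN1 at 0.88 ± 0.10. Lysosome and autophagy genes rose in 5 of 22 and fell in 1 (7 and 1 adjusted over the list alone), with GABARAPL1 at 0.96 ± 0.18 and MAP1LC3B at 0.64 ± 0.15. The camera adjusted p of the last 5 lists was 3.03e-06, 0.000230, 0.000233, 0.00148 and 0.00307. These 9 lists kept their call with an estimated correlation, with adjusted p from 0.0297 to 0.0349. By sample name, with the same 4 arrays and fold changes but a wider pooled spread, all 9 were called at the preset correlation. Of these, G2/M genes kept the call (10 fell and 0 rose; adjusted p = 0.00519 with an estimated correlation). Histones did not (0 of 60 past the threshold; adjusted p = 0.641 with an estimated correlation), nor did G1/S genes (7 fell; adjusted p = 0.137 with an estimated correlation) or ATF4 genes (5 rose and 1 fell; adjusted p = 0.144 with an estimated correlation). The other 5 lists had 1 to 3 members higher and an adjusted p from 0.144 to 0.368 with an estimated correlation.

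The muscle lists moved in a few members. Among 15 myogenic regulators MYMK, which drives myoblast fusion, fell (-1.76 ± 0.20), as did SOX8 (-0.76 ± 0.12) and MYOD1 (-0.71 ± 0.15), while MYF5 rose (1.15 ± 0.18). With 1 up and 3 down (2 and 3 adjusted over the list alone) the list was called lower (adjusted p = 0.0406, and adjusted p = 0.207 with an estimated correlation). The fusion target FGFR4 (-0.66 ± 0.11), the fetal acetylcholine receptor subunit CHRNG (-1.29 ± 0.15), MYL11 (-1.18 ± 0.16) and TPM1 (-1.02 ± 0.12) also fell, although the lists of PAX3-FOXO1 targets and muscle structural genes were not called. Of 24 sterol and fatty acid genes 6 rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 0.00672, and adjusted p = 0.0863 with an estimated correlation). Members included MSMO1 at 1.09 ± 0.11 and FADS2 at 1.04 ± 0.12. Of 72 genes of oxidative phosphorylation 14 fell and 0 rose (14 and 0 adjusted over the list alone; adjusted p = 0.00160, and adjusted p = 0.359 with an estimated correlation). Members included UQCRB at -1.78 ± 0.21 and ATP5F1C at -1.14 ± 0.11. Apoptosis regulators were called higher with 4 of 32 members up and 3 down (5 and 3 adjusted over the list alone; adjusted p = 0.0406, and adjusted p = 0.0573 with an estimated correlation). Members included BAK1 at 1.02 ± 0.16 and CASP8 at 0.83 ± 0.19. Of 42 MYC and ribosome biogenesis genes 5 rose, among them NIP7 (0.80) and RRS1 (0.68), and 3 fell (11 and 4 adjusted over the list alone; adjusted p = 0.0458, and adjusted p = 0.359 with an estimated correlation). Of 28 homologous recombination and Fanconi genes CHEK2 (-0.64) and BLM (-0.59) fell and 0 rose (2 and 0 adjusted over the list alone; adjusted p = 0.0430, and adjusted p = 0.433 with an estimated correlation). By sample name the lists of myogenic regulators (1 up and 0 down; adjusted p = 0.287), apoptosis regulators (adjusted p = 0.0780) and MYC genes (adjusted p = 0.0640) were not called. Sterol, oxidative phosphorylation and homologous recombination genes were called at the preset correlation only (adjusted p from 0.144 to 0.544 with an estimated correlation). MYMK (adjusted p = 0.0671), SOX8 (0.306), MYOD1 (0.274), FGFR4 (0.0616), SLC11A2, DUSP1, MAP1LC3B, H4C1, H2AC15, RRS1, BLM and KDM4D did not pass the threshold by sample name, while MYF5, CHRNG, MYL11 and TPM1 did. In all, limma called 2047 genes, 931 higher and 1116 lower, of which 90 rose and 181 fell at least 2-fold. These 4 arrays sit in the same groups under both labels, but the spread of the other arrays enters the fit, and the count was 725 with groups by sample name and 826 from these 4 arrays alone. Without shControl replicate 1 it was 1179, without shKDM4B replicate 1 it was 1039 and without shKDM4B replicate 2 it was 1095.

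The siRNA comparison asks the same of siRNA against KDM4C, with the same limit on effects outside the target. KDM4C itself had a fold change of -0.23 ± 0.19 by title (adjusted p = 0.651, n = 2 and 2) and did not pass the threshold. In simulated data by title this comparison recovered 91.0% of 2-fold and 52.2% of 1.5-fold changes. The simulation gave all arrays equal noise, so these shares do not cover the dependence on single arrays given below. The largest rises were in PGM2L1 (1.19 ± 0.21), MSTN, the gene of the muscle growth inhibitor myostatin (1.17 ± 0.14), the microfibril gene MFAP5 (1.17 ± 0.16), MYMK (1.08 ± 0.20), NCEH1 (1.07 ± 0.16) and RAB30 (1.06 ± 0.21). The largest falls were in MANBAL (-1.06 ± 0.12), EPB41L5 (-1.04 ± 0.15), the splicing gene HNRNPM (-0.96 ± 0.11), DZIP1 (-0.95 ± 0.18), SCLY (-0.90 ± 0.10) and the mitochondrial fusion gene MFN2 (-0.88 ± 0.12). The giant muscle protein gene TTN (0.95 ± 0.18), DCX (0.92 ± 0.19) and the fusion target CXCR4 (0.61 ± 0.12) rose and JARID2 (-0.86 ± 0.14) fell, while MYL11 had a fold change of 0.70 ± 0.16 (adjusted p = 0.0566). KDM4B was at -0.28 ± 0.23 (adjusted p = 0.650).

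Replication-dependent histones had the lowest camera p after siKDM4C, with 2 of 60 lower, H2AC4 (-0.82 ± 0.17) and H2AC8 (-0.70 ± 0.15), and 18 lower adjusted over the list alone (adjusted p = 2.61e-22, and adjusted p = 0.0630 with an estimated correlation). Of 482 numbered ZNF genes 2 rose and 0 fell, ZNF548 (1.05 ± 0.16) and ZNF480 (0.77 ± 0.15), and 12 rose adjusted over the list alone (adjusted p = 3.43e-05, and adjusted p = 0.228 with an estimated correlation). Among 41 interferon-stimulated genes IFIT3 rose (0.92 ± 0.17) and 4 rose adjusted over the list alone (adjusted p = 0.0299, and adjusted p = 0.228 with an estimated correlation). Ribosomal protein, heat shock, oxidative phosphorylation and MYC lists were called lower and homologous recombination genes higher with 0 members past the threshold (2 heat shock genes lower adjusted over the list alone, 0 members of the others), at median changes of -0.08, -0.22, -0.10, -0.10 and 0.14 log2. Their adjusted p was 0.000468, 0.000571, 0.00256, 0.00979 and 0.0471, and their adjusted p with an estimated correlation was 0.620, 0.228, 0.620, 0.529 and 0.620. By title limma called 81 genes, 47 higher and 34 lower (2446 at an unadjusted p under 0.05). By sample name 7 lists were called, with 0 members past the threshold in the histone, ribosomal protein and interferon lists (medians -0.64, -0.24 and 0.24 log2). PAX3-FOXO1 targets (median -0.22, adjusted p = 0.00656) and myogenic regulators (-0.49, adjusted p = 0.0131) were called lower by sample name, against medians of 0.01 and 0.06 by title. The other lists called were oxidative phosphorylation (-0.09) and lysosome genes (0.21), and 0 of the 7 kept their call (lowest adjusted p = 0.726 with an estimated correlation). By title, siControl replicate 2 and both siKDM4C replicates by sample name are QC6352 arrays of Rh30. By title siControl replicate 1 is a DMSO array. Across genes, the fold changes by sample name had a Pearson r of 0.430 with those of QC6352 in Rh41, against 0.114 by title. The count by title rested on single arrays, with 1789 without siKDM4C replicate 1, 9 without siKDM4C replicate 2, 14 without siControl replicate 1 and 8 without siControl replicate 2, and it was 0 from the 4 arrays alone and 19 with the replicate number as a block. By sample name limma called 0 genes (2203 at an unadjusted p under 0.05). The 5 genes with the smallest p by sample name, none past the threshold, were WDR7 (-1.31), TIMM9 (-0.85), ZNF394 (1.00), PCDH9 (1.13) and CCDC88C (1.63). If the titles hold, the comparison by sample name sets a DMSO and a QC6352 array against QC6352 arrays. Its values then do not measure KDM4C siRNA.

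The next comparison asks what QC6352 does in Rh30. By title, the tubulin folding cofactor TBCA dropped by 4.86 log2 (SE 0.11, adjusted p = 1.24e-15, n = 3 and 3), from 9.99 to 5.13, with NMRK1 (-4.44 ± 0.17), the kinetochore gene SKA2 (-3.97 ± 0.11), the histone H2AC8 (-3.95 ± 0.12), HS2ST1 (-3.79 ± 0.17) and ANK2 (-3.68 ± 0.12). The largest rises were in RFPL4A (4.26 ± 0.21) and its close paralog RFPL4AL1 (4.04 ± 0.19), whose probes were not checked for cross-hybridization, the kinase SGK1 (4.11 ± 0.21), the lysosomal protein CD68 (3.62 ± 0.11), the nuclear receptor NR4A1 (3.19 ± 0.15) and RND1 (3.10 ± 0.18). MYOG fell by 2.63 log2 (SE 0.10, adjusted p = 3.94e-13), from 11.77 ± 0.05 (SD) to 9.14 ± 0.17. Of the drug's targets KDM4A rose (0.49 ± 0.10, adjusted p = 0.000865), KDM4D fell (-0.80 ± 0.23, adjusted p = 0.00923) near background, and KDM4B (-0.19) and KDM4C (0.11) did not pass the threshold.

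**Figure D2:**
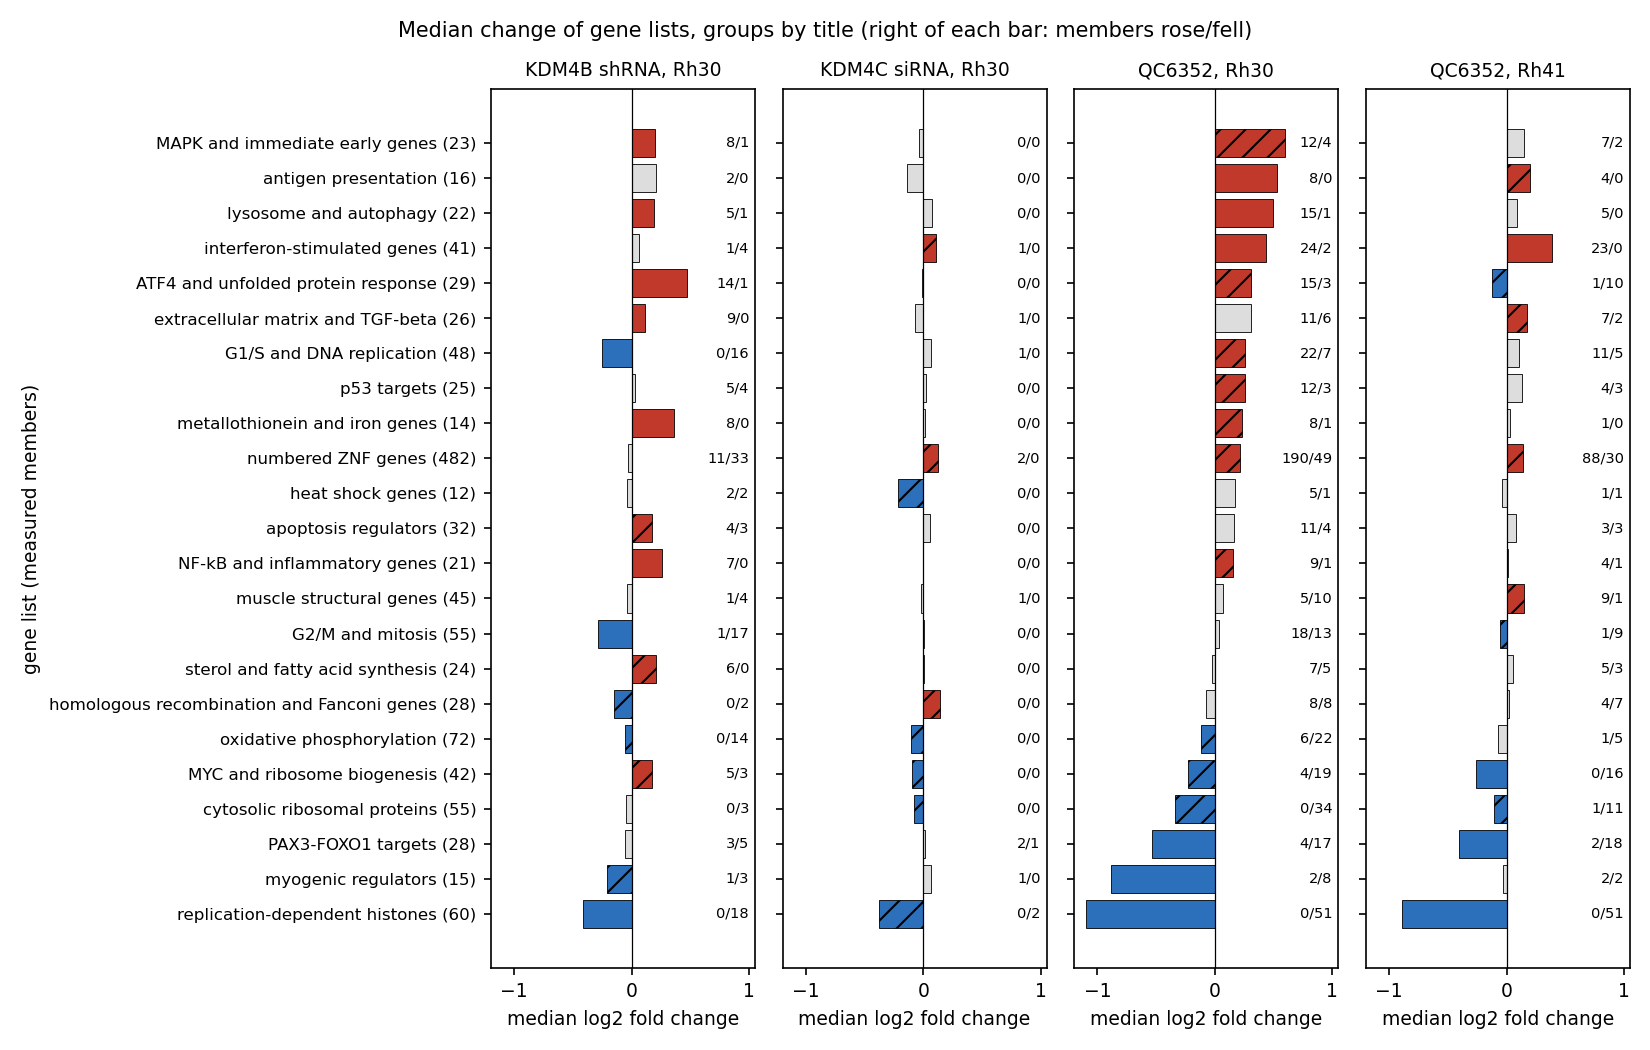
Bars give the median log2 fold change of each of 23 gene lists called in at least 1 of 4 comparisons, with groups by title; red and blue mark lists called with a median above or below 0, hatching marks calls lost with an estimated correlation, grey marks lists not called, and the numbers are members that rose and fell. Replication-dependent histones have a median below 0 in all 4 comparisons, from -0.37 to -1.10.

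Histone genes fell with QC6352 in Rh30 in 51 of 60 cases and rose in 0 (53 and 0 adjusted over the list alone; adjusted p = 3.38e-31; median -1.10), with H2BC8 at -3.32 ± 0.11. Many histone genes are close paralogs whose probes were not checked for cross-hybridization. Their counts, here and in the other comparisons, may not be separate measurements. Myogenic regulators fell in 8 of 15 cases and rose in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.000397). Members included MYMK at -2.20 ± 0.16 and SOX8 at -1.60 ± 0.10. PAX3-FOXO1 targets fell in 17 of 28 and rose in 4 (17 and 4 adjusted over the list alone; adjusted p = 2.85e-05). Members included KCNN3 at -1.56 ± 0.09. This list and that of myogenic regulators share SOX8 and MYOD1, so their falls are not fully separate results. Interferon-stimulated genes rose in 24 of 41 and fell in 2 (24 and 2 adjusted over the list alone; adjusted p = 0.000319). Members included IFIT2 at 2.46 ± 0.15 and IFIT3 at 2.18 ± 0.14. Lysosome and autophagy genes rose in 15 of 22 and fell in 1 (15 and 2 adjusted over the list alone; adjusted p = 0.00103). Members included MCOLN1 at 0.98 ± 0.10 and CTSB at 0.89 ± 0.09. Antigen presentation genes rose in 8 of 16 and fell in 0 (9 and 0 adjusted over the list alone; adjusted p = 0.00186). Members included HLA-E at 1.41 ± 0.12 and HLA-F at 1.03 ± 0.14. These 6 lists kept their call with an estimated correlation (adjusted p from 0.0167 to 0.0470). By sample name 0 members of the 6 lists passed the threshold. Medians were then -0.04 for histones, 0.21 for myogenic regulators, 0.21 for PAX3-FOXO1 targets, 0.07 for interferon-stimulated genes, 0.01 for lysosome genes and -0.03 for antigen presentation genes. Of these, histones were called (adjusted p = 0.00291, and adjusted p = 0.746 with an estimated correlation).

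The other 10 lists called in Rh30 lost their call with an estimated correlation. Ribosomal proteins fell in 34 of 55 cases and rose in 0 (34 and 0 adjusted over the list alone; adjusted p = 2.30e-09, and adjusted p = 0.189 with an estimated correlation). Members included RPL10A at -1.62 ± 0.12 and RPL22L1 at -1.27 ± 0.12. Of 42 MYC and ribosome biogenesis genes 19 fell and 4 rose (20 and 4 adjusted over the list alone; adjusted p = 0.00103, and adjusted p = 0.189 with an estimated correlation). Members included NPM1 at -1.01 ± 0.13 and UTP20 at -0.97 ± 0.14. Numbered ZNF genes rose in 190 and fell in 49 of 482 (197 and 49 adjusted over the list alone; adjusted p = 0.00118, and adjusted p = 0.189 with an estimated correlation). Members included ZNF878 at 2.34 ± 0.19 and ZNF10 at 2.26 ± 0.26. The list of ATF4 and the unfolded protein response had 15 of 29 members higher and 3 lower (15 and 3 adjusted over the list alone; adjusted p = 0.00347, and adjusted p = 0.189 with an estimated correlation). Members up included the stress genes ATF3 (3.05 ± 0.13) and DDIT3 (1.53 ± 0.14). ATF4 itself, named after its values were seen, fell (-1.61 ± 0.09). MAPK genes rose in 12 and fell in 4 of 23 (14 and 4 adjusted over the list alone; adjusted p = 0.0101, and adjusted p = 0.0952 with an estimated correlation). Members included JUNB at 2.12 ± 0.13 and DUSP5 at 1.93 ± 0.13. Targets of p53 rose in 12 and fell in 3 of 25 (12 and 4 adjusted over the list alone; adjusted p = 0.0227, and adjusted p = 0.0681 with an estimated correlation). Members included PPM1D and GDF15 both at 1.41. NF-kB genes rose in 9 and fell in 1 of 21 (9 and 1 adjusted over the list alone; adjusted p = 0.0227, and adjusted p = 0.189 with an estimated correlation). Members included IER3 at 1.82 ± 0.10 and TRAF1 at 1.48 ± 0.13. Metallothionein and iron genes rose in 8 and fell in 1 of 14 (8 and 1 adjusted over the list alone; adjusted p = 0.0187, and adjusted p = 0.239 with an estimated correlation). Members included SLC30A1 at 1.30 ± 0.10 and FTL at 1.27 ± 0.11. G1/S genes rose in 22 and fell in 7 of 48 (23 and 8 adjusted over the list alone; adjusted p = 0.0263, and adjusted p = 0.299 with an estimated correlation). Members up included the cyclin CCNE2 (1.26 ± 0.13) and the nuclease EXO1 (1.04 ± 0.14). Among its members that fell were the replicative helicase genes MCM2 (-0.78 ± 0.13), MCM5 (-0.54 ± 0.11) and MCM6 (-0.66 ± 0.11), named after their values were seen. Oxidative phosphorylation genes fell in 22 and rose in 6 of 72 (22 and 6 adjusted over the list alone; adjusted p = 0.0130, and adjusted p = 0.469 with an estimated correlation). Members included NDUFV3 at -1.82 ± 0.12 and NDUFV2 at -1.78 ± 0.23.

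By sample name 10 lists were called in Rh30, histones among them. ATF4 genes were called lower instead of higher (adjusted p = 0.0230, and adjusted p = 0.706 with an estimated correlation), with 0 members past the threshold and a median of 0.04 above 0. Ribosomal proteins (median 0.02), MYC genes (-0.04) and oxidative phosphorylation genes (-0.01) were called lower with 0 members past the threshold. ZNF genes (6 up and 0 down), MAPK genes, p53 targets, NF-kB genes, metallothionein genes and G1/S genes were not called, the last 5 with 0 members past the threshold. Called by sample name but not by title were hypoxia and glycolysis genes (0 up and 1 down), heat shock genes, muscle structural genes and matrix genes, all lower, and homologous recombination genes (1 up and 0 down), higher. The medians of the hypoxia, muscle structural and matrix lists, 0.0033, 0.018 and 0.0050, lay above 0, as did those of the ATF4 and ribosomal protein lists. Camera compares a list with the other genes, and the median change of all genes was 0.14 here by sample name. A list called lower thus lies below the other genes and need not lie below 0. None of the 10 kept its call (lowest adjusted p = 0.309 with an estimated correlation).

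Muscle structural genes were not called, with MYL1 up (2.10 ± 0.13) and KLHL41 (-1.71 ± 0.13) and CHRNG (-1.10 ± 0.12) down. By title limma called 6427 genes, 3517 higher and 2910 lower, 534 and 749 of them at least 2-fold, and 3337 at least 1.5-fold. By sample name it called 89, 81 higher and 8 lower, with TELO2 (1.16) and HK1 (-0.95) the largest each way, 4019 without QC6352 replicate 1 and 0 to 19 without any other array, and centring the arrays turned the share higher from 91.0% to 33.3%.

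In Rh41, where the labels do not conflict, QC6352 raised ANKRD1, a stretch-responsive muscle gene (3.06 ± 0.13, n = 3 and 3, adjusted p = 2.06e-11), IFIT1 (2.98 ± 0.18), FSD1L (2.58 ± 0.18), IFIT3 (2.28 ± 0.14), ALPK2 (2.20 ± 0.09) and NUAK1 (2.07 ± 0.11). NMRK1 fell by 3.48 log2 (SE 0.17), with H2BC14 (-3.01 ± 0.20), TBCA (-2.92 ± 0.11), NLGN1 (-2.87 ± 0.20), the chloride transporter CLCN5 (-2.78 ± 0.09) and FAM72A (-2.73 ± 0.19), a member of a family of close paralogs. KDM4A rose (0.51 ± 0.10, adjusted p = 0.00156) and KDM4D fell (-0.95 ± 0.23, adjusted p = 0.00542), while KDM4C was at 0.43 ± 0.15 (adjusted p = 0.0583) and KDM4B at -0.34 (adjusted p = 0.250).

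Histones fell in 51 of 60 cases in Rh41 and rose in 0 (54 and 0 adjusted over the list alone; adjusted p = 2.93e-41; median -0.89), with H3C11 at -2.32 ± 0.14. Interferon-stimulated genes rose in 23 of 41 and fell in 0 (23 and 1 adjusted over the list alone; adjusted p = 8.93e-11). PAX3-FOXO1 targets fell in 18 of 28 and rose in 2 (20 and 4 adjusted over the list alone; adjusted p = 5.70e-10). Members included the nitric oxide synthase NOS1 at -1.89 ± 0.12 and the receptor kinase ALK at -1.26 ± 0.17. MYC and ribosome biogenesis genes fell in 16 of 42 and rose in 0 (20 and 1 adjusted over the list alone; adjusted p = 7.18e-08). Members included SLC19A1 at -1.20 ± 0.12 and NOP16 at -0.75 ± 0.11. These 4 lists kept their call with an estimated correlation (adjusted p from 0.000543 to 0.0499). By sample name, with the same arrays and fold changes, 30 histones fell, 18 interferon-stimulated genes rose, 9 PAX3-FOXO1 targets fell and 1 rose, and 8 MYC and ribosome biogenesis genes fell. All 4 lists were then called at the preset correlation and none kept its call (adjusted p from 0.0923 to 0.214 with an estimated correlation).

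The 7 other lists called in Rh41 lost their call with an estimated correlation. Muscle structural genes rose in 9 and fell in 1 of 45 (11 and 1 adjusted over the list alone; adjusted p = 0.0205, and adjusted p = 0.161 with an estimated correlation). Members included TPM1 at 1.47 ± 0.10, the calcium pump ATP2A1 at 0.84 ± 0.16 and MYL1 at 0.70 ± 0.13. Matrix and TGF-beta genes rose in 7 and fell in 2 of 26 (7 and 2 adjusted over the list alone; adjusted p = 0.0104, and adjusted p = 0.141 with an estimated correlation). Members included THBS1 at 1.46 ± 0.11 and CCN1 at 1.18 ± 0.08. ATF4 genes fell in 10 and rose in 1 of 29 (10 and 1 adjusted over the list alone; adjusted p = 0.00914, and adjusted p = 0.270 with an estimated correlation). Members included TRIB3 at -0.72 ± 0.12 and ERN1 at -0.67 ± 0.17. G2/M genes fell in 9 and rose in 1 of 55 (9 and 1 adjusted over the list alone; adjusted p = 0.0299, and adjusted p = 0.594 with an estimated correlation). Members included HMMR at -1.60 ± 0.12 and CDC20 at -0.76 ± 0.09. Ribosomal proteins fell in 11 and rose in 1 of 55 (14 and 1 adjusted over the list alone; adjusted p = 0.000552, and adjusted p = 0.570 with an estimated correlation). Members included RPL10A at -0.86 ± 0.12 and RPL26L1 at -0.80 ± 0.11. Numbered ZNF genes rose in 88 and fell in 30 of 482 (106 and 32 adjusted over the list alone; adjusted p = 0.0151, and adjusted p = 0.415 with an estimated correlation). Members included ZNF404 at 1.14 ± 0.19 and ZNF442 at 0.97 ± 0.17. Antigen presentation genes rose in 4 and fell in 0 of 16 (4 and 0 adjusted over the list alone; adjusted p = 0.0299, and adjusted p = 0.157 with an estimated correlation). Members included TAP2 at 0.86 ± 0.10 and TAPBP at 0.72 ± 0.10. By sample name antigen presentation genes were not called (3 up and 0 down; adjusted p = 0.0582), and the other 6 lists were called in the same direction and lost the call (lowest adjusted p = 0.200 with an estimated correlation). MYL1, ERN1, RPL10A, KDM4D and EYA1 did not pass the threshold by sample name.

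The list of myogenic regulators was not called, with SOX8 lower (-1.58 ± 0.10), EYA1 lower (-0.44 ± 0.10) and MEF2A higher (0.72 ± 0.11). With groups by title limma called 3479 genes, 1923 higher and 1556 lower, 129 and 256 of them at least 2-fold, and 1386 at least 1.5-fold. With groups by sample name, which leave these 6 arrays in place but widen the pooled spread, it called 1537, and 796 to 905 without each of the 6 in turn.

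The interaction term tests whether the drug's effect differs between lines. The difference, Rh41 minus Rh30, was largest for ANKRD1 (3.78 ± 0.19), HS2ST1 (3.57 ± 0.24), MSTN (3.49 ± 0.17), NEGR1 (3.11 ± 0.18) and SKA2 (2.92 ± 0.15). ANKRD1 rose by 3.06 in Rh41 against -0.72 in Rh30, whereas MSTN was at -0.02 in Rh41 and fell by 3.51 in Rh30. On the other side stood RFPL4AL1 (-4.15 ± 0.27), RFPL4A (-3.97 ± 0.30), SGK1 (-3.24 ± 0.30), NR4A2 (-3.00 ± 0.26) and RND1 (-3.00 ± 0.25), where RFPL4A and RFPL4AL1 were near background in Rh41. Of 15 myogenic regulators 8 differed, all with a higher signed log2 change in Rh41 (8 and 0 adjusted over the list alone; median difference 0.45). Higher and lower responses refer to the signed log2 change here and below, so a higher response can be a smaller fall. MYOG, at 11.77 log2 in Rh30 and 11.80 in Rh41 in DMSO, changed by -2.63 in Rh30 and 0.28 in Rh41. Responses were lower in Rh41 than in Rh30 for 16 of 29 ATF4 genes and higher for 1 (21 and 2 adjusted over the list alone; median -0.45), lower for 9 of 25 p53 targets and higher for 1 (11 and 4 adjusted over the list alone; -0.37) and lower for 10 of 23 MAPK genes and higher for 4 (12 and 4 adjusted over the list alone; -0.42). They were lower for 7 of 22 lysosome genes (9 adjusted over the list alone; -0.23) and 5 of 21 NF-kB genes (5 adjusted over the list alone; -0.21), and higher for 0 of either. Responses were higher in Rh41 for 26 of 60 histones and lower for 3 (29 and 4 adjusted over the list alone; 0.37), higher for 15 of 55 ribosomal proteins and lower for 0 (18 and 0 adjusted over the list alone; 0.22) and higher for 11 of 45 muscle structural genes and lower for 3 (12 and 3 adjusted over the list alone; 0.11). The histone medians were -0.89 in Rh41 and -1.10 in Rh30, and those of ribosomal proteins -0.11 and -0.34, so both lists fell less in Rh41. The camera adjusted p of the 9 lists ran from 2.13e-07 to 0.0259. None of these 9 lists kept its call with an estimated correlation (lowest adjusted p = 0.0871 with an estimated correlation). By sample name 5 of the 9 medians had the opposite sign, those of myogenic regulators (-0.34, 0 higher and 3 lower), histones (-0.91, 0 higher and 9 lower), ribosomal proteins (-0.14), MAPK genes (0.08) and lysosome genes (0.15). Histones were then called lower (adjusted p = 5.48e-12, and adjusted p = 0.588 with an estimated correlation) and lysosome genes higher (adjusted p = 0.0233, and adjusted p = 0.588 with an estimated correlation). In all, 7 lists were called, of which interferon-stimulated genes, matrix and TGF-beta genes and muscle structural genes kept their call (adjusted p = 0.0485 with an estimated correlation for each). The others called were PAX3-FOXO1 targets, lower (0 higher and 10 lower, adjusted p = 6.19e-08, and 0.242 with an estimated correlation), and antigen presentation genes, higher (adjusted p = 0.0106, and 0.593 with an estimated correlation). Myogenic regulators, ribosomal proteins and ATF4, p53, MAPK and NF-kB genes were not called by sample name (lowest adjusted p = 0.319). By title 3534 genes differed, 1862 above and 1672 below 0, and 762 by sample name, 3471 without Rh30 QC6352 replicate 1 and 420 to 479 without each other array of the 4 groups.

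**Figure D3:**
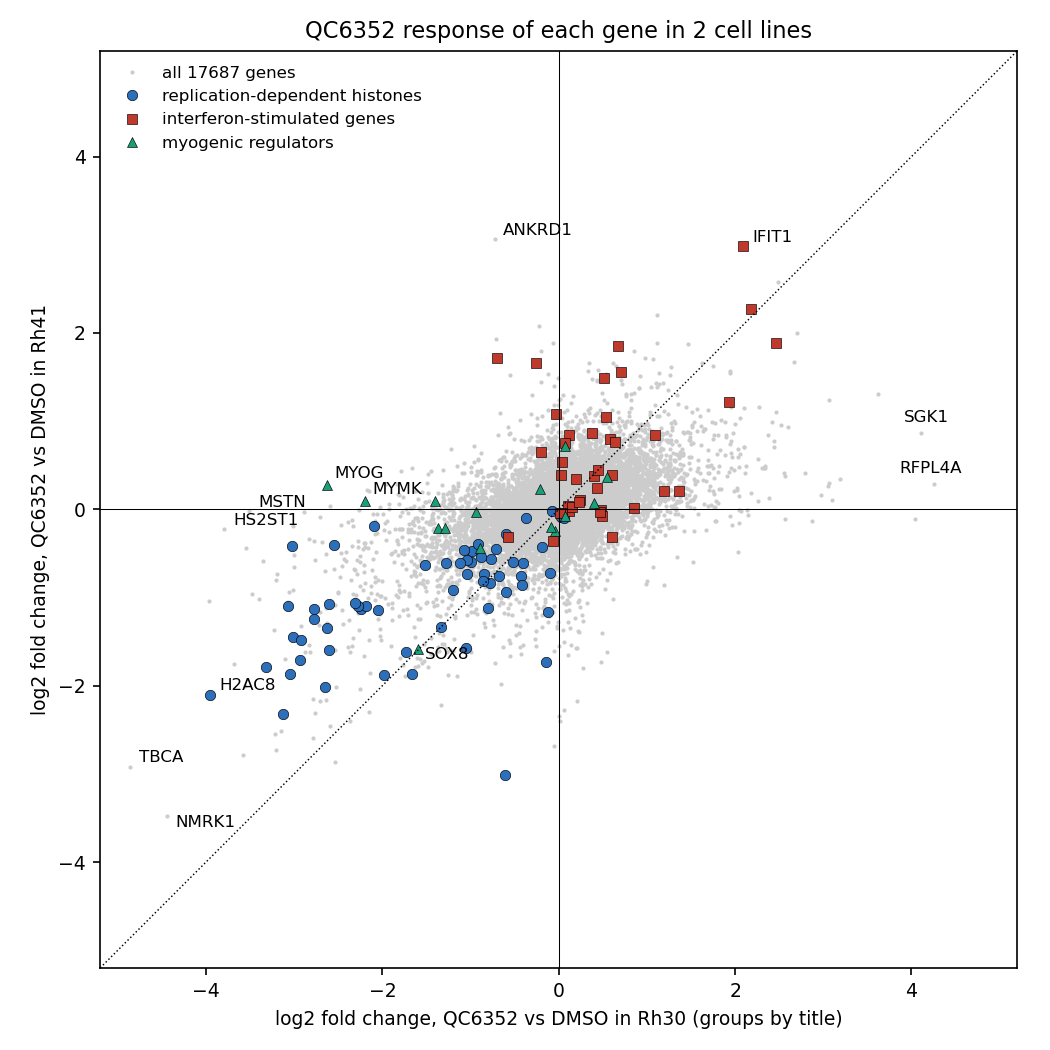
Each point is a gene at its log2 fold change of QC6352 over DMSO in Rh30 (horizontal, groups by title) and Rh41 (vertical), with all 17687 genes in grey, histones as blue circles, interferon-stimulated genes as red squares and myogenic regulators as green triangles; the dotted line marks equal change. MYOG lies at -2.63 and 0.28, away from the line, and TBCA at -4.86 and -2.92.

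The calls of QC6352 in both lines overlapped. By title 1115 genes rose in both, where 382 would be expected, and 967 fell in both, where 256 would be expected, while 190 moved in opposite directions against 626 expected. The match of Rh30 to Rh41 was among the values seen before the titles were preferred. The excess by title is therefore not a separate test of agreement between the lines. The heparin-binding growth factor HBEGF (2.70 in Rh30, 2.00 in Rh41), STC1 (2.67, 1.67), IFIT1, IFIT2, IFIT3 and FSD1L rose in both, and NMRK1, TBCA, CLCN5 (-3.59, -2.78) and the paralogs FAM72A, FAM72B and FAM72D fell in both. By sample name 11 genes rose in both (3.93 expected) and 0 fell in both (0.31 expected), while 3 moved in opposite directions (3.50 expected).

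The drug and the KDM4B hairpin in Rh30 shared 381 rises (185 expected) and 428 falls (184 expected), beside 423 opposite calls (375 expected), by title. CLDN1 (2.27 with the drug, 2.18 with the hairpin), SGK1 (4.11, 1.70), CNTNAP1 (2.03, 1.64), ELOVL4, CLDN4 and TRAF1 rose in both. MYMK (-2.20, -1.76), H4C1 (-2.78, -1.45), IFTAP, the copper transporter ATP7A, CEP63 and JAKMIP2 fell in both. Across genes the fold changes had a Pearson r of 0.184. The shared count of 809 was 338 from each comparison's own arrays, 467 without shControl replicate 1, 440 without shKDM4B replicate 1, 437 without shKDM4B replicate 2 and 2 by sample name. With siKDM4C the drug shared 24 rises (9.35 expected), including IFIT3, CCNE2 and CLDN1, and 14 falls (5.59 expected), including JARID2, H2AC4, H2AC8 and VGLL2, beside 17 opposite calls (14.5 expected). Across genes the Pearson r of these fold changes was 0.0104. That count of 38 was 3 without siControl replicate 1, 1 without siControl replicate 2, 572 without siKDM4C replicate 1, 1 without siKDM4C replicate 2, 25 without Rh30 DMSO replicate 2 and 0 by sample name. The groups of these comparisons share no arrays, but their tests are not independent. All arrays entered the same fit, so the same residual spread of a gene enters both tests. The expected numbers assume independent calls and can therefore be too low. Opposite calls also exceeded them, with the hairpin (423 against 375) and with siKDM4C (17 against 14.5). From each comparison's own arrays the count of 38 was 0.

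In DMSO, Rh41 exceeded Rh30 by title in ANKRD29 (6.66 ± 0.11), SERPINI1 (6.62 ± 0.13), the aryl hydrocarbon receptor AHR (6.56 ± 0.12), STATH and ERVW-1. It was lower in MGAM2 (-6.42 ± 0.14), MGST1 (-6.33 ± 0.11), H2AC11 (-6.06 ± 0.12), FILIP1L (-5.87 ± 0.09) and MFAP5 (-5.53 ± 0.13), and the lower level of most of these genes was near background. By title 10180 genes differed, 7202 higher and 2978 lower in Rh41, and by sample name 10939. The median of all genes differed by 0.19 log2 between the lines by title, and centring the arrays lowered the share higher from 70.7% to 45.9%.

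Marker lists of epithelial, blood, endothelial and fibroblast cells were not called in any of the 4 treatment comparisons (lowest adjusted p = 0.131). With QC6352 in Rh30 4 of 13 epithelial markers rose and 0 fell (5 and 0 adjusted over the list alone), 3 of 13 blood markers rose and 0 fell (2 and 0 adjusted over the list alone), 1 of 9 endothelial markers rose and 1 fell, and 1 of 10 fibroblast markers rose and 0 fell (the same adjusted over the list alone for both). The members were CLDN4 (1.91), KRT8 (0.46), CLDN3 (0.40) and KRT7 (0.39), CD68 (3.62), CD3E (0.50) and CSF1R (0.50), TIE1 (0.74) and PECAM1 (-1.03), and THY1 (0.89). In Rh41 the epithelial KRT18 rose (0.45; 0 adjusted over the list alone), as did CD68 (1.31) and LYZ (0.81) of the blood list and PDGFRB (0.44) of the fibroblast list, and the fibroblast marker FAP fell (-1.11). With the KDM4B hairpin CLDN4, LAPTM5 (0.56) and TIE1 (0.65) rose and 0 markers fell, and after siKDM4C 0 markers passed the threshold. By sample name 0 markers passed it with QC6352 in Rh30 and 1, CLDN4, with the hairpin. These genes were named after their values were seen except CD68 in Rh30 and CLDN4.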

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

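The tests of the labels and of cycling cells were chosen after the results they measure were seen. The first rule tried for cycling cells with QC6352, the sign of the G1/S median, would have argued against that explanation in both lines. It was replaced by the camera call of the list, which must also hold with an estimated correlation.

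The 10 Rh30 arrays with 2 labels decide what the Rh30 comparisons measure. Titles that are wrong beside correct sample names are argued against, since the residual SD was larger by sample name for 78.6% of genes (median 0.205 against 0.163 log2). Sample names that are wrong beside correct titles may explain the conflict, since array medians span at most 0.0362 log2 within a group by title, against 0.270 by sample name and a smallest gap of 0.198 between the 3 levels of medians. Another measure separates the labels poorly. The closest array of a contested array lay in its group by title for 7 of the 10 and in its group by sample name for 5. Some contested arrays share a group under both labels, and a match between them counts for both. Both sets of labels being wrong in part stays open and was not tested.

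The histone list was called lower under every treatment by title, a call lost with an estimated correlation for siKDM4C and, by sample name, for all 4 comparisons. Compression of bright probe sets is argued against for QC6352, since the histone median lay at percentile 0 of 10000 random lists matched on mean signal in both lines, whose lowest medians were -0.12. These lists were drawn from other genes and do not carry the correlation among histone genes. Fewer cycling cells stay open in both lines with QC6352, since neither the G1/S nor the G2/M list was called with an estimated correlation. G1/S genes had a median of 0.26 in Rh30 with 22 up and 7 down (adjusted p = 0.0263, and adjusted p = 0.299 with an estimated correlation), and G2/M genes in Rh30 had 18 up and 13 down (adjusted p = 0.626). G1/S genes in Rh41 had a median of 0.11 with 11 up and 5 down (adjusted p = 0.398). G2/M genes in Rh41, in favour of fewer cycling cells, had 1 up and 9 down (adjusted p = 0.0299, and adjusted p = 0.594 with an estimated correlation). Under the KDM4B hairpin fewer cycling cells may hold, since the larger of the medians of the G1/S and G2/M lists was -0.25, although by sample name the G1/S call was lost with an estimated correlation (adjusted p = 0.137 with an estimated correlation). An effect of KDM4 inhibition on histone transcripts stays open as a hypothesis, as no test here separates it from the open explanations.

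Myogenic regulators responded differently to QC6352 in the 2 lines, with a median difference of 0.45 log2 (Rh41 minus Rh30) and MYOG at 2.91 ± 0.14, although the call of the list was lost with an estimated correlation (adjusted p = 0.0871 with an estimated correlation). After quantile normalization of all arrays 8 members still differed past the threshold, but this does not decide on separate normalization of the arrays. By title the DMSO and QC6352 arrays of each line share a level of medians. A constant offset between the lines thus cancels in each fold change with or without quantile normalization. Starting levels over 1 log2 apart or close to background are argued against for most of these members. Of the 8, 7 started within 1 log2 of each other and more than 2 log2 above background, with MYF5 the exception. These levels were not centred on the array medians, which differ between the lines, and MYMK (8.79 in Rh30, 7.93 in Rh41) lay near the limit. Smaller differences in starting level stay open. A difference between the lines in how this program responds may remain, as a hypothesis found and tested on the same data and dependent on the titles, since the median difference was -0.34 by sample name.

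The test of the difference between lines pointed to 3534 genes by title and 762 by sample name. The genes with the largest differences were ANKRD1 (3.78), HS2ST1 (3.57), MSTN (3.49), NEGR1 (3.11), SKA2 (2.92), RFPL4AL1 (-4.15), RFPL4A (-3.97), SGK1 (-3.24), NR4A2 (-3.00) and RND1 (-3.00). RFPL4AL1 and RFPL4A were near background in Rh41, which limits the size of their differences. Lists called at the preset correlation by title, with their median difference, were muscle structural genes (0.11), p53 targets (-0.37), ATF4 and unfolded protein response (-0.45), NF-kB genes (-0.21), MAPK genes (-0.42), lysosome and autophagy genes (-0.23), histones (0.37) and ribosomal proteins (0.22). None of these lists kept its call with an estimated correlation (lowest adjusted p = 0.0871 with an estimated correlation), and the medians of MAPK genes, lysosome genes, histones and ribosomal proteins had the opposite sign by sample name. Of 3739 transcript probe sets without a gene name, data outside the comparisons of named genes, 1016 differed between QC6352 and DMSO in Rh30 by title, 619 higher and 397 lower, and 529 in Rh41, 280 higher and 249 lower. The hairpin changed 153 of them and siKDM4C 5.

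Other splits of the same arrays were counted. Splits of 3 against 3 arrays number 10, too few for a share under 0.05. By title 1 of 10 gave as many calls as the real split for QC6352 in Rh30 (6427, highest other 0), in Rh41 (3479, highest other 0) and in DMSO between lines (10180, highest other 0). By sample name it was 3 of 10 for QC6352 in Rh30 (89, highest other 790), which points to a structure of the arrays that these groups do not follow, 1 of 10 in Rh41 (1537, highest other 0) and 1 of 10 in DMSO (10939, highest other 0). For the difference between lines 3 of 100 splits drawn from 200 gave as many by title (3534, highest other 4152) and 3 of 100 by sample name (762, highest other 1643). The other splits as large kept the drug groups of 1 line apart and mixed those of the other, Rh41 mixed by title (4152 and 4053) and Rh30 mixed by sample name (1643 and 1057). A drug effect in 1 line alone thus gives as many calls, and these splits do not test whether the responses of the lines are equal, which a share under 0.05 had been set to show. Chance is not excluded by them.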

How the results depend on the processing

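The repeats of the alternatives with groups by title, the groups by title for the KDM4B hairpin and the block of crossed replicate numbers were chosen after the data were seen. By title, quantile normalization, centring and testing every probe set left every count of genes within 1.5 times its value. By sample name, testing every probe set did so. The cause of each change given here was not tested, except that groups with 1 array fewer give a test fewer arrays. Without siControl replicate 2 by sample name, the siRNA arrays left are, by title, DMSO replicate 3 and QC6352 replicates 2 and 3 of Rh30. That count for siKDM4C thus sets DMSO against QC6352 arrays if the titles hold. Leaving out an array of a pair assumes that the lone array left varies like the other groups. Genes near the background of 3.64 to 4.01 log2, such as KDM4D, KDM4E, CNTRL and RFPL4A in Rh41, are limited by signal over background.

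With groups by sample name, the count for the KDM4B hairpin of 725 became 1999 with array weights, 2047 by title and 241 to 369 without 1 array. The count of 0 for siKDM4C became 1 after quantile normalization, 1 after centring, 81 by title and 0 to 3219 without 1 array. The count of 89 for QC6352 in Rh30 became 24 after quantile normalization, 18 after centring, 166 without dim probe sets, 156 with trend and robust, 5854 with array weights, 0 from the compared arrays alone, 0 with the replicate block, 6427 by title and 0 to 4019 without 1 array. The count of 1537 in Rh41 became 5134 with array weights, 4409 from its own arrays, 3479 by title and 796 to 905 without 1 array. The difference between lines of 762 became 6298 with array weights, 1424 from its own arrays, 3534 by title and 420 to 3471 without 1 array. The DMSO count of 10939 became 7080 without dim probe sets. The 11 calls of QC6352 shared by both lines became 2 after quantile normalization, 2 after centring, 23 without dim probe sets, 817 with array weights, 0 from their own arrays, 0 with the replicate block, 4 at 1.5-fold, 2082 by title and 0 to 221 without 1 array. The 2 calls shared by QC6352 and the hairpin became 1 after quantile normalization, 0 after centring, 6 without dim probe sets, 251 with array weights, 0 from their own arrays, 0 with the replicate block, 809 by title and 0 to 109 without 1 array. The 0 shared with siKDM4C became 38 by title and 0 to 77 without 1 array. The 39 calls of gene lists became 1 with an estimated correlation.

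With groups by title, the hairpin count of 2047 became 826 from its own arrays, 1111 at 1.5-fold and 1039 to 1557 without 1 array. The siKDM4C count of 81 became 341 without dim probe sets, 438 with trend and robust, 9 with array weights, 0 from its own arrays, 19 with the replicate block, 46 with crossed numbers as the block and 8 to 1789 without 1 array. Of the 1789 genes without siKDM4C replicate 1, 80 were among the 81. At 1.5-fold the counts were 3337 for QC6352 in Rh30, 1386 in Rh41, 6060 in DMSO and 736 for the calls shared by both lines. The 809 calls shared by QC6352 and the hairpin became 338 from their own arrays, 334 at 1.5-fold and 437 to 826 without 1 array. The 38 shared with siKDM4C became 136 without dim probe sets, 175 with trend and robust, 1 with array weights, 0 from their own arrays, 6 with the replicate block, 21 at 1.5-fold and 1 to 572 without 1 array. The 50 calls of gene lists became 19 with an estimated correlation. With the replicate block the counts by title were 1620 for the hairpin, 6172 and 3103 for QC6352 in Rh30 and Rh41, and 3136 for the difference between lines.

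Of the named gene values by title, 59 reversed with groups by sample name, 78 kept their direction without passing the threshold and 99 kept both. For siKDM4C the reversed log2 fold changes were MSTN -1.68, MYMK -0.85, MANBAL 0.0013, EPB41L5 0.013, MFN2 0.19, KDM4C 0.23, KDM4D -0.50, KDM4B 0.33, DCX -0.38, MEF2A -0.093, TCF12 -0.49, MYL11 -0.036 and TRIM63 0.40. For QC6352 in Rh30 they were TBCA 0.037, NMRK1 0.40, SKA2 0.024, HS2ST1 0.29, ANK2 0.58, KDM4A -0.035, KDM4D 0.70, KDM4E 0.69, MYOG 0.20, SOX8 0.19, KCNN3 0.21, MYMK 0.44, MYL1 -0.19, UTP20 0.045, PPM1D -0.10, GDF15 -0.27, DDIT3 -0.39, IFIT3 -0.10, HLA-F -0.15, TRAF1 -0.32, FTL -0.21, MCOLN1 -0.017, CTSB -0.14, ZNF10 -0.089, RPL10A 0.21, RPL22L1 0.17, IFIT1 -0.00088, HBEGF -0.29, STC1 -0.037, FAM72A 0.24, FAM72D 0.35, FAM72B 0.33, CLDN4 -0.36, IFTAP 0.23, ATP7A 0.44, JAKMIP2 0.31, HYCC2 -0.13, JARID2 0.28, TBCD 0.022, VGLL2 0.37 and SNRPB 0.067. For the difference between lines they were HS2ST1 -0.51, MSTN -0.42, NEGR1 -0.59, SKA2 -1.07 and SGK1 0.26. None of the named gene values reversed with quantile normalization, centring, trend and robust, the compared arrays alone or the replicate block. These left 233, 236, 234, 201 and 221 values with the same direction and side of the threshold, and 3, 0, 0, 34 and 15 no longer past it. Leaving out 1 array gave 1193 such values, 82 no longer past the threshold and 10 reversed, all of KDM4 genes that did not pass it. Those ranges were -0.087 to 0.12 for KDM4A with the hairpin, with -0.029 also below 0, and -0.015 to 0.29 for KDM4A, -0.16 to 0.57 for KDM4D and -0.17 to 0.28 for KDM4E with siKDM4C, with -0.075 for KDM4E also below 0. With QC6352 in Rh30 they were -0.038 to 0.35 for KDM4C, -0.10 to 0.075 for KDM4E, with 0.0053 also above 0, and -0.33 to 0.032 for KDM4B.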

Other observations

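The list of apoptosis regulators was not called with QC6352 in either line. Of its 32 members 11 rose, 4 fell and 17 did not pass the threshold in Rh30 by title (12 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.194), and 3 rose, 3 fell and 26 did not pass in Rh41 (3 and 3 adjusted over the list alone; adjusted p = 0.790). By sample name 0 members passed in Rh30, and 1 rose and 1 fell in Rh41 (the same adjusted over the list alone in both lines). The single members that follow, with values by title, were named after their values were seen and do not stand for the list. PMAIP1, which encodes the BH3-only protein NOXA, rose by 2.44 log2 (SE 0.12, n = 3 and 3, limma adjusted p = 1.9e-11) in Rh30 and by 0.71 (SE 0.12) in Rh41. BCL2L11, which encodes the BH3-only protein BIM, rose by 1.69 (SE 0.09) in Rh30 and 1.13 (SE 0.09) in Rh41. The responses differed between the lines for PMAIP1 (-1.73 ± 0.17) and for BCL2L11 (-0.56 ± 0.13). BCL2, which opposes cell death, fell in Rh41 (-0.91 ± 0.14) and was at 0.01 ± 0.14 in Rh30.

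Of 19 other demethylases of the JmjC class 6 rose, 6 fell and 7 did not pass with QC6352 in Rh30 by title (7 and 7 adjusted over the list alone; camera adjusted p = 0.972), and 2 rose, 3 fell and 14 did not pass in Rh41 (2 and 3 adjusted over the list alone; adjusted p = 0.790). By sample name 0 of the 19 passed in Rh30 (5 rose and 1 fell adjusted over the list alone), and 1 rose and 0 fell in Rh41 (0 and 0 adjusted over the list alone). By title, among the 19 and named after their values were seen, KDM5A rose in Rh30 (1.29 ± 0.09) and Rh41 (0.43 ± 0.09), while RIOX2 (-1.09 and -0.56) and JMJD1C (-0.96 and -0.37) fell in both lines. Of 17 targets of Notch, Hedgehog and Wnt signals 3 rose, 2 fell and 12 did not pass in Rh30 (3 and 2 adjusted over the list alone; adjusted p = 0.321), and 4 rose, 2 fell and 11 did not pass in Rh41 (4 and 3 adjusted over the list alone; adjusted p = 0.939). Members past the threshold, chosen in the same way, included AXIN2 (2.31 ± 0.16) and HES1 (1.97 ± 0.12) in Rh30, HHIP in Rh30 (-1.63 ± 0.10) and Rh41 (-1.45 ± 0.10), and LGR5 in Rh41 (-2.69 ± 0.11). By sample name 0 of the 17 passed in Rh30, and 1 rose and 2 fell in Rh41 (the same adjusted over the list alone in both lines).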
